A study of Homo sapiens with 12 samples.

How the data were processed

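RNA of H9 cells in RSeT medium was sequenced as stranded poly(A) libraries from 80 to 130 ng of total RNA, in 3 groups of 4 replicates (ASO-Ctr, sO-L1 and ASO-L1), 12 libraries in all. The deposited count table holds raw counts per gene with duplicate reads removed, per the labels. According to the submitters' processing notes, Trim Galore 0.4.0, TopHat2 2.0.13 and featureCounts of Subread 1.5.0 were used with the genome build hg19, and the gene annotation is not given in the sources used here. Removing duplicates lowers the counts of abundant genes more than those of rare genes, so levels of abundant genes are compressed by an unknown amount. A second table deposited by the authors holds log2 normalized values, per the labels with a cutoff of 0.2 and a batch correction. Another deposited table gives, for ASO-L1 against sO-L1, log2 fold changes and average log2 expression, with a p-value and an adjusted p-value that the authors computed. It also has a moderated statistic and log odds, other deposited values by the authors that were not used. The count table has 53717 genes, of which 35768 had a count in some library, the log2 table has 20187 and the comparison table has 20856. A spreadsheet had turned 26 gene symbols of the count table and 24 of the log2 table into dates, and these genes were tested but not named. No entry counts LINE1, and reads of repeats were not analysed here. Many 8C genes belong to families of near-identical copies (PRAMEF, TRIM, MBD3L, RFPL and DUX genes), and ribosomal protein genes have many processed pseudogenes, so reads shared between copies make the level of a single member uncertain.

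The batch correction was checked on the values. In the 10548 genes with a mean count of at least 200, log2 values (offset 0.5) centred on their group were correlated between libraries of different groups. The 12 pairs of the same replicate number had r from 0.214 to 0.726, each above the threshold of 0.1 set for pairing, against a median of -0.224 for pairs of different numbers, and in 21 of 24 tests a library's best match was its own number. In the deposited log2 table the median SD between the means of the replicate numbers was 0.00940, against 0.0713 in uncorrected log2 values. The replicate number was therefore kept as a block. Replicates of a group differed by more than counting error, at a chi-squared of 3.00 to 29.0 per gene in genes with at least 20 counts in a pair of libraries, and 0 pairs of libraries were identical. Differences within a replicate number are given below as the difference of log2 CPM (prior count 2) between libraries of the same number.

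Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood F-tests, two-sided) on all 12 libraries, with group and replicate number in the model. The filter kept 17264 genes, the biological coefficient of variation was 0.0634, and 6 residual degrees of freedom were moderated by a prior of 10.8. Adjusted p-values of genes are Benjamini-Hochberg values over these genes, called under 0.05. Intervals of fold changes are nominal 95% intervals from a normal approximation. They are somewhat narrower than the degrees of freedom of the F-test would give. Levels are CPM per library with TMM scaling, as mean ± SD over 4 libraries. In all, 22 gene lists with 760 members, written from general knowledge, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 66 tests. The lists are 8C genes, naive, primed and core pluripotency, PRC2 subunits, developmental regulators bound by PRC2, nucleolar and RNA polymerase I genes, ribosomal proteins, interferon and double-stranded RNA response, p53 targets, integrated stress response, trophectoderm, amnion, primitive endoderm, mesoderm and primitive streak, neuroectoderm, fibroblast, mitochondrially encoded genes, transposon silencing, proliferation, cholesterol synthesis and immediate early genes. Beside camera stand camera with an estimated correlation, fry, and the count of members adjusted over the list alone. The groups, comparisons, tests, lists and alternatives were set before the data were examined.

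Genes were named by a rule. For each comparison it takes the 10 largest positive and 10 largest negative log2 fold changes among genes called, with an average log2 CPM of at least 1 and the same direction in all 4 replicate numbers. It adds up to 4 called members of each list with the smallest adjusted p, and always, where measured, ZSCAN4, LEUTX, TPRX1, DUXA, KLF17, DPPA3, POU5F1, NANOG, SOX2, L1TD1, EZH2, EED, SUZ12, NCL, TRIM28 and CDKN1A. Genes on the Y chromosome and XIST were never named. Where 5 or fewer members of a list were called in 1 direction, all of them are named, and these, the 8C gene KHDC1, values of a gene in a comparison where the rule did not pick it, and the host genes and hypoxia targets of the closing observations were chosen after their values were seen. Of the many genes that the rule picks, the text gives a part.

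Alternatives were: no replicate block; size factors of DESeq2; upper quartile scaling; the Wald test of DESeq2 1.42.0; no filter on low counts (at least 1 count in all); 1 CPM in 4 libraries; only the 2 groups compared. Also run were limma-trend on the authors' log2 table, 1 surrogate variable from sva 3.50.0 with the replicate block, and 16 fits that left out a replicate number or a single library. Limma-trend had no replicate block, since that table was already corrected for batch. The degrees of freedom used by the correction were not counted, so its p-values can be too small. The sum of the 8C genes under the filter was added after the data were seen. Under DESeq2 size factors and upper quartile scaling the median of all genes moved by less than 0.1 on the log2 scale. The overlap of both ASO-L1 comparisons was set beside 20 simulations of unchanged groups that share libraries. Genomic span, transcript length and GC content came from GENCODE release 29, which describes another genome build than the deposited counts, so genes were matched by symbol, 14497 of 17264, and no coordinates are given. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 was used for the exact permutation tests and the figures.

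The fit was tested on simulated data of the same depth, with a spread fitted as a trend over expression level and with 17044 genes. Only 48 to 50 genes were changed at each fold, far fewer than were called in the data. The shares below therefore need not carry over to the real comparisons. For ASO-L1 against ASO-Ctr it called 52.0% of genes changed 1.25-fold, 77.1% at 1.5-fold, 97.9% at 2-fold and 100% at 3-fold, with 12 false calls among 172. Against sO-L1 the shares were 56.0, 81.3, 95.8 and 98.0%, with 8 false calls among 170, and for the pair of unchanged groups 0 genes were called. Camera called the 1 simulated list of 30 genes shifted 1.3-fold and 0 of 20 unshifted lists, in simulated genes that vary independently of one another.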

Results

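Poly(A) RNA was sequenced from H9 cells, an established human embryonic stem cell line, kept in RSeT medium. This medium is meant to hold such cells in a naive-type state related to the embryo before implantation. Whether the cells were in that state was not tested here. The cells received 1 of 3 fluorescein-labelled oligonucleotides at 25 nM by lipofection, and fluorescent cells were sorted 48 h later. ASO-L1 is antisense to RNA of LINE1, a retrotransposon family that fills a large share of the human genome. sO-L1 is the sense oligo of the same element, and ASO-Ctr is a non-targeting antisense oligo. Each group had 4 libraries, 12 in all. Trans-ISRIB, which counters the block on translation made by the integrated stress response, was present at 0.7 uM, together with the caspase inhibitor emricasan and Y-27632, and these were taken out after 24 h. Reads counted in genes came to 22.8, 41.5, 32.2 and 35.3 M in ASO-Ctr replicates 1 to 4, 34.8, 55.1, 34.3 and 31.1 M in sO-L1, and 27.4, 40.8, 29.5 and 34.9 M in ASO-L1. At these depths 3 reads, the number that a count of 0 allows, equal 0.0545 to 0.131 CPM (counts scaled to the size of the library). Mitochondrially encoded genes took 5.59 to 6.48% of the reads of each library. Such floors, and the confidence intervals given with fold changes, cover the error of counting and of the model only, since reads without molecular identifiers are not independent molecules. The labels do not say that the replicates were separate cultures, so every p-value measures only the spread between these samples, and that spread can be technical.

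The series asks what LINE1 does for the genes of the 8-cell embryo (8C genes), whose expression marks a totipotent-like state. The deposited count table has 53717 genes and 0 entries for LINE1, so the level of the oligo's target was not analysed here and whether ASO-L1 lowered it is not known from these values. Gene values below are means in CPM ± SD over 4 libraries per group, and log2 fold changes with their standard error (SE) from edgeR's quasi-likelihood test with the replicate number as a block. Adjusted p-values of genes are from that test with Benjamini-Hochberg adjustment over 17264 genes. Those of gene lists are from camera, a test of a list against the other genes, adjusted over 22 lists and 3 comparisons. Camera was used with a preset correlation of 0.01 between the genes of a list, and with a correlation estimated from the data no list was called in any comparison. Genes named because 5 or fewer of a list were called in 1 direction, and values of a gene in a comparison whose rule for naming did not pick it, were chosen after the values were seen.

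Most 8C genes lay at or near the limit of detection in all 3 groups. Of 57 listed 8C genes 54 were in the table. Of these 51 lay under the filter on low counts, with at most 0.316 CPM in any library, and 31 had 0 reads in every library. LEUTX and DUXA, homeobox factors of the first wave of embryonic transcription, had 0 reads in each of the 12 libraries. ZSCAN4, a telomere and 2-cell/8C marker, had 9 reads over all libraries and at most 0.131 CPM in 1 of them, and TPRX1, another homeobox factor, had 44 reads and at most 0.316 CPM. Summed over the 51 members under the filter, ASO-L1 libraries held 0.504 ± 0.0928 CPM from 68 reads, ASO-Ctr libraries 0.526 ± 0.217 CPM from 69 reads and sO-L1 libraries 0.547 ± 0.214 CPM from 87 reads (SD, n = 4 each). An exact two-sided permutation test, chosen after the data were seen, gave p = 0.943 for ASO-L1 against ASO-Ctr, p = 0.83 against sO-L1 and p = 0.857 for sO-L1 against ASO-Ctr, where the smallest possible value was 0.0286. No rise in the sum of these 51 genes was detected, and the smallest rise that could have been seen at this depth was not computed. KLF17, a marker of the naive state and of the embryo before implantation, was also under the filter, with 52 reads and at most 0.483 CPM.

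The other 3 listed 8C genes could be tested. CCNA1, a meiotic A-type cyclin, was at 3.58 ± 0.835 CPM with ASO-L1 and 2.83 ± 0.933 CPM with ASO-Ctr, a 1.28-fold difference (95% interval 1.06 to 1.53; log2 0.35, SE 0.13, adjusted p = 0.0426, edgeR). It was not called against sO-L1 (log2 0.25, adjusted p = 0.129). SLC34A2, a phosphate transporter, was at 0.681 ± 0.165 CPM with ASO-L1 and 0.374 ± 0.131 CPM with sO-L1 (log2 0.83, SE 0.32, adjusted p = 0.0442), and was not called against ASO-Ctr (log2 0.50, adjusted p = 0.218). KHDC1, with 2497 reads over all libraries, was not called in either comparison. The call of CCNA1 was lost in 12 of 16 fits that left out a replicate number or a single library (adjusted p = 0.0258 to 0.286), without the replicate block (adjusted p = 0.272) and with DESeq2 (adjusted p = 0.0763). That of SLC34A2 was lost in 9 of 16 such fits (adjusted p = 0.0360 to 0.175), without the block (adjusted p = 0.0570) and with DESeq2 (adjusted p = 0.0877). Adjusted over the list alone, edgeR called 0 of the 3 genes in each comparison, with 1, 1 and 0 of them at an unadjusted p under 0.05. DESeq2 called 0, 0 and 0 of them over all genes, and limma, run on the authors' log2 table, called 1, 2 and 0. That table was already corrected for batch and limma had no replicate block, so limma can call too many genes. Camera gave the list an adjusted p of 0.565 for ASO-L1 against ASO-Ctr, 0.524 against sO-L1 and 0.896 for sO-L1 against ASO-Ctr. Fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, gave adjusted p = 0.0439, 0.0253 and 0.851.

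ASO-L1 against ASO-Ctr asks what the antisense LINE1 oligo changes relative to a non-targeting oligo. CCR7, ANXA1, HSPB8, AHNAK, FLNC, DDIT3 and ATF5 were among the 10 largest rises. CCR7, a chemokine receptor, rose 71.7-fold (95% interval 47.6 to 108), to 8.98 ± 6.34 CPM from 0.114 ± 0.0900 CPM, a control level near the floor, so that the size of the fold is uncertain. ANXA1, a phospholipid-binding protein of inflammation, rose 47.6-fold (33.6 to 67.5) to 10.9 ± 6.98 CPM from 0.213 ± 0.149 CPM, also close to the floor. The small heat shock protein HSPB8 rose 7.89-fold to 13.5 ± 7.52 CPM. The actin cross-linker FLNC rose from 24.3 ± 1.60 to 170 ± 108 CPM (log2 2.67, SE 0.23, adjusted p = 1.87e-07), the scaffold protein AHNAK from 5.22 ± 1.22 to 37.7 ± 24.5 CPM (log2 2.71, SE 0.17) and the intermediate filament VIM from 122 ± 21.0 to 415 ± 74.4 CPM (log2 1.78, SE 0.11, adjusted p = 9.87e-09). Among the largest falls were FRMPD4, a synaptic scaffold, 3.17-fold lower at 0.875 ± 0.263 against 2.85 ± 0.532 CPM, and SLC16A3, a lactate transporter, 3.05-fold lower at 4.12 ± 2.09 against 14.2 ± 11.1 CPM (adjusted p = 8.68e-06 and 1.03e-05). Each of these genes moved the same way in all 4 replicate numbers. In total edgeR called 7652 of 17264 genes (44.3%), 3668 higher and 3984 lower, of which 429 and 246 differed by over 2-fold. The median size of a called change was 0.37 on the log2 scale.

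Stress genes rose together. Of 32 measured genes of the integrated stress response, the programme switched on by phosphorylated eIF2-alpha through ATF4, 26 rose, 4 fell and 2 were not called, with a mean log2 difference of 0.61 ± 0.11 (SD over 4 replicate numbers, all positive). ATF5, a transcription factor of that programme, rose 5.87-fold (4.94 to 6.97), from 20.3 ± 1.74 to 124 ± 47.4 CPM (adjusted p = 1.03e-09). DDIT3, which encodes the pro-apoptotic factor CHOP, rose 5.94-fold to 25.3 ± 11.1 CPM, the pseudokinase TRIB3 rose 4.51-fold to 48.0 ± 23 CPM and ATF3 rose 3.56-fold to 46.0 ± 14.4 CPM. The 4 called lower were CTH, ALDH1L2, PCK2 and DDIT4. With 1 surrogate variable DDIT4 and PCK2 turned to higher (log2 0.196 and 0.0480, adjusted p = 0.0948 and 0.633). DDIT4 fell mostly in replicate 1, from 72.6 to 37.7 CPM, and rose in replicate 4, from 19.6 to 20.7 CPM. PCK2 and DDIT4 lost their call in 8 and 12 of 16 leave-out fits (highest adjusted p = 0.121 and 0.575), and ALDH1L2 lost it without replicate 2 (adjusted p = 0.0674) and without replicate 3 (adjusted p = 0.0863), all 3 also without the replicate block (adjusted p = 0.176, 0.433 and 0.0820). Of 30 targets of p53, 21 rose and 9 were not called (mean log2 difference 0.72 ± 0.18). CDKN1A, the cell cycle inhibitor p21, rose 5.23-fold from 5.89 ± 3.16 to 30.3 ± 13.9 CPM (adjusted p = 4.32e-09), PHLDA3, an inhibitor of AKT, rose 2.94-fold to 66.3 ± 23.5 CPM, and SESN2, a member of both lists, rose 2.34-fold. Of 15 measured immediate early genes 11 rose, 1 fell and 3 were not called (mean 0.47 ± 0.11), with JUN 2.10-fold higher at 135 ± 15.3 CPM and KLF2 2.40-fold higher. The 1 that fell was FOS (log2 -0.30, adjusted p = 0.00549; without the replicate block adjusted p = 0.190). Adjusted over the list alone, 27 stress response genes were higher and 4 lower, 22 p53 targets were higher, and 11 immediate early genes were higher and 2 lower. Camera gave adjusted p = 6.37e-19 for the stress response, 5.93e-19 for p53 targets and 2.62e-05 for immediate early genes. These were adjusted p = 0.162, 0.165 and 0.165 with an estimated correlation.

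Genes of cholesterol synthesis fell. Of 24 genes 22 fell and 2 were not called, or 23 lower when adjusted over the list alone, with a mean log2 difference of -0.56 ± 0.23 (camera, adjusted p = 3.85e-14, and adjusted p = 0.367 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, was 1.78-fold lower at 309 ± 90.2 against 539 ± 71.6 CPM (log2 -0.84, SE 0.08, adjusted p = 7.39e-07). INSIG1, a sterol-regulated sensor of the endoplasmic reticulum, was 1.95-fold lower at 60.7 ± 14.2 against 117 ± 6.80 CPM (log2 -0.96, SE 0.09, adjusted p = 2.91e-07).

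**Figure D1:**
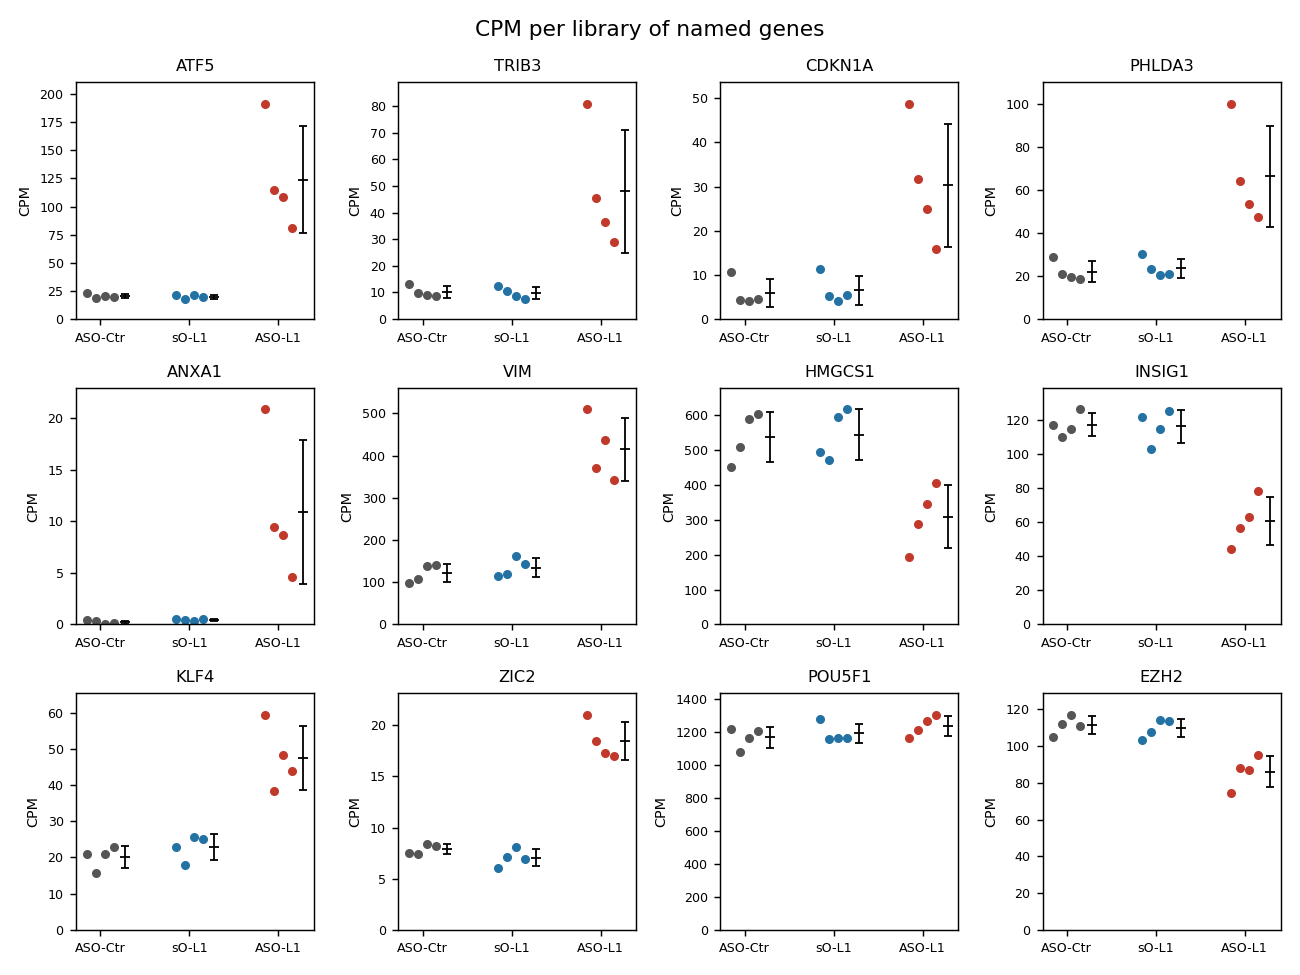
CPM (y axis, linear, from 0) of 12 named genes in each library, one panel per gene, with ASO-Ctr, sO-L1 and ASO-L1 along the x axis, a point for each of the 4 replicates from 1 to 4 and a bar for the mean ± SD. ATF5 lies at 124 ± 47.4 CPM in ASO-L1 against 20.3 ± 1.74 CPM in ASO-Ctr and 19.8 ± 1.66 CPM in sO-L1, while the 3 groups of POU5F1 overlap.

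Ribosome genes rose slightly but widely. Of 78 ribosomal protein genes 56 rose, 3 fell and 19 were not called (57 and 3 adjusted over the list alone), with a mean log2 difference of 0.16 ± 0.09. RPLP1 was 1.26-fold higher at 901 ± 39.8 against 717 ± 48.5 CPM (adjusted p = 2.30e-06). The 3 that fell were RPL26, RPL12 and RPL3, at log2 -0.35, -0.27 and -0.21. With 1 surrogate variable RPL3 turned to 0.0135 (adjusted p = 0.867). All 57 genes of the nucleolus and RNA polymerase I were measured, of which 35 rose, 3 fell and 19 were not called (37 and 3 adjusted over the list alone), with a mean of 0.15 ± 0.04. RRP12, a ribosome export factor, rose 1.43-fold from 95.5 ± 3.89 to 137 ± 13.1 CPM, and POLR1B, the second largest subunit of RNA polymerase I, rose 1.34-fold (adjusted p = 1.24e-06 and 3.43e-06). The 3 that fell were UTP20 and HEATR1, of the small subunit processome, 1.46-fold and 1.33-fold lower, and the helicase DDX21 (log2 -0.31). NCL, the main nucleolar RNA-binding protein, differed 1.06-fold (log2 0.08, adjusted p = 0.0437). That call was lost in 10 of 16 leave-out fits (adjusted p = 0.000572 to 0.244), without the replicate block (adjusted p = 0.298) and with DESeq2 (adjusted p = 0.0607). Camera gave adjusted p = 9.61e-09 for ribosomal proteins and 1.44e-05 for the nucleolar list, and adjusted p = 0.596 and 0.165 with an estimated correlation.

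Markers of pluripotency moved in both directions. Of 22 measured naive markers 9 rose and 6 fell (11 and 6 adjusted over the list alone), with camera adjusted p = 0.181. KLF4, a factor of the naive state, rose 2.35-fold from 20.1 ± 3.04 to 47.5 ± 8.88 CPM, KLF5 rose 2.12-fold and DPPA3, a maternal factor, 1.34-fold to 40.9 ± 4.13 CPM, while the growth factor FGF4 fell by 0.55 on the log2 scale (adjusted p = 4.92e-05, edgeR). Of 21 primed markers 8 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.892), among them VIM, described above, ZIC2, 2.34-fold higher at 18.4 ± 1.84 CPM, the adhesion protein NLGN4X, 1.84-fold lower, and the DNA methyltransferase DNMT3B, 1.42-fold lower. Of 20 core pluripotency genes 5 rose and 8 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.565). TERF1, a telomere-binding protein, was 1.53-fold lower at 518 ± 55.6 against 793 ± 59.9 CPM. The 5 that rose were FGF2, ZSCAN10, POLR3G, DPPA4 and DPPA2, by 0.37, 0.24, 0.28, 0.19 and 0.25 on the log2 scale. The call of DPPA2 was lost in 4 of 16 leave-out fits (highest adjusted p = 0.0758) and without the replicate block (adjusted p = 0.281). The central factors were not called: POU5F1 at log2 0.09 (adjusted p = 0.128), NANOG at 0.05 (adjusted p = 0.338) and SOX2 at -0.07 (adjusted p = 0.131). POU5F1 was called higher without replicate 1 (adjusted p = 9.44e-05) and without ASO-L1 replicate 1 (adjusted p = 0.000228), and SOX2 lower without replicate 1 (adjusted p = 0.0238). L1TD1, an RNA-binding protein descended from LINE1 ORF1, was lower by a small amount (log2 -0.10, adjusted p = 0.0285), a call lost in 10 of 16 leave-out fits (adjusted p = 0.00417 to 0.153) and without the block (adjusted p = 0.0752).

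The title of the series names the Polycomb complex PRC2, which places the repressive mark H3K27me3. Of 14 measured subunits 2 rose, 2 fell and 10 were not called, the same counts adjusted over the list alone (camera adjusted p = 0.896). EZH2, the catalytic subunit, was 1.29-fold lower at 86.0 ± 8.59 against 111 ± 4.97 CPM (log2 -0.37, SE 0.05, adjusted p = 1.15e-05). EED, which reads the mark, was 1.16-fold higher (adjusted p = 0.00745), and SUZ12 was at log2 0.05 (adjusted p = 0.365). The other 2 called were PHF1, higher at log2 0.38, and EZH1, lower at -0.20 (adjusted p = 0.0220), whose call was lost in 7 of 16 leave-out fits (highest adjusted p = 0.124) and without the block (adjusted p = 0.107). TRIM28, a corepressor at transposons, was not called (log2 0.06, adjusted p = 0.195; called without replicate 1, adjusted p = 0.00901). Of 150 developmental regulators bound by PRC2 in embryonic stem cells only 26 were expressed enough to test, and 16 of these rose and 2 fell (16 and 2 adjusted over the list alone), with a mean log2 difference of 0.69 ± 0.34 that was 1.18 in replicate 1 and 0.39 to 0.60 in the others. Several stayed low: MSX2, a homeobox factor of several germ layers, was at 0.879 ± 0.372 against 0.0953 ± 0.0490 CPM and HOXB3 at 1.33 ± 0.794 against 0.309 ± 0.0718 CPM (adjusted p = 0.000135 and 9.98e-05), and GATA2 rose 1.78-fold to 2.49 ± 0.425 CPM. The filter on low counts keeps a gene that passes in the libraries of a single group. Members near the floor in the controls, such as MSX2, could thus enter through ASO-L1 alone, and members at the floor cannot fall. Part of the excess of rises can come from this. The 2 that fell, SOX10 and PAX9, lost their calls in 10 of 16 and 8 of 13 leave-out fits (highest adjusted p = 0.172 and 0.151). Camera called the list (adjusted p = 0.000677, and adjusted p = 0.373 with an estimated correlation), and not with 1 surrogate variable added to the model (adjusted p = 0.0747).

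Of the lists for other lineages, camera called only mesoderm and primitive streak with the planned model. Of its 6 measured genes 3 rose (3 higher and 1 lower adjusted over the list alone; mean 0.28 ± 0.09; camera adjusted p = 0.00651, and adjusted p = 0.165 with an estimated correlation). They were CER1, a secreted inhibitor of Nodal, 2.06-fold higher at 213 ± 72.7 CPM, the homeobox factor MIXL1, 1.53-fold higher, and the VEGF receptor KDR (log2 0.38, adjusted p = 0.0271). KDR lost its call in 6 of 16 leave-out fits (highest adjusted p = 0.211), and with 1 surrogate variable it turned to lower (log2 -0.0703, adjusted p = 0.747). It rose in replicates 1 and 2, from 19.6 to 38.7 and from 12.2 to 17.7 CPM, and fell in replicate 3, from 10.2 to 8.83 CPM. Without the replicate block the list was not called (adjusted p = 0.443), nor on the authors' log2 table (adjusted p = 0.0557). Of 12 trophectoderm markers 5 rose (ABCG2, KRT18, GATA2, KRT8 and PGF; 5 adjusted over the list alone; camera adjusted p = 0.161), with the transporter ABCG2 2.44-fold higher. The list was called higher with 1 surrogate variable (adjusted p = 0.0341) and by fry (adjusted p = 0.00306). It was not alone in this. Fry also called naive, amnion and fibroblast markers higher (adjusted p = 0.00127, 0.0358 and 0.0199). Core pluripotency, transposon silencing and proliferation genes were called lower by fry (adjusted p = 0.0146, 0.00306 and 0.0318). KRT8 and PGF lost their calls without replicate 2 (adjusted p = 0.0538 and 0.0691) and without replicate 3 (adjusted p = 0.0629 and 0.0507), and KRT8 also without the block (adjusted p = 0.263). Of 6 amnion markers BMP4 fell by 0.33 on the log2 scale (1 lower adjusted over the list alone; camera adjusted p = 0.752), and lost its call without replicate 1 (adjusted p = 0.0816), without ASO-Ctr replicate 1 (adjusted p = 0.0805) and without ASO-Ctr replicate 4 (adjusted p = 0.121). Of 11 primitive endoderm markers SPARC, LINC00261, FOXA2 and FLRT3 rose and PDGFRA, COL4A2, LAMA1 and COL4A1 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.931, pointing down although the median of 0.12 and the mean of 0.26 were positive). FLRT3 lost its call in 5 of 16 leave-out fits (highest adjusted p = 0.131), COL4A1 without replicate 2 (adjusted p = 0.0543), and these 2 and FOXA2 without the block (adjusted p = 0.125, 0.270 and 0.167). Of 8 neuroectoderm markers NES, PAX6 and SOX3 rose and DCX, TUBB3 and NCAM1 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.931), with SOX3 lost without the block (adjusted p = 0.0604).

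Among 13 fibroblast markers TAGLN, an actin-binding protein of smooth muscle, rose 2.61-fold to 26.1 ± 3.77 CPM and the mesenchymal factor TWIST1 rose 12.7-fold to 3.89 ± 2.69 CPM, while the collagen COL1A2 was 1.66-fold lower at 36.6 ± 4.65 against 61.3 ± 8.71 CPM. The others called were S100A4 and CTGF, higher, and FBN1, COL5A1 and LOX, lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.370). S100A4, CTGF and LOX lost their calls in 7, 8 and 7 of 16 leave-out fits (highest adjusted p = 0.0801, 0.170 and 0.163), and COL5A1 lost its call without replicate 2 (adjusted p = 0.106) and without ASO-L1 replicate 2 (adjusted p = 0.0522). Without the block, CTGF and LOX were not called (adjusted p = 0.281 and 0.0941). Interferon and double-stranded RNA response genes moved both ways, with 6 of 31 higher and 8 lower, the same counts adjusted over the list alone (camera adjusted p = 0.931). IFITM1 rose 1.35-fold and BST2 was 1.78-fold lower, both antiviral membrane proteins. Of 30 transposon silencing genes 3 rose and 11 fell, the same adjusted over the list alone (camera adjusted p = 0.277). SAMHD1, a nucleotide hydrolase that restricts LINE1, was 1.78-fold lower at 62.7 ± 13 against 111 ± 1.61 CPM and CBX5, which encodes HP1-alpha, fell by 0.32 on the log2 scale. The 3 that rose were APOBEC3C, DNMT3L and TET2, with TET2 lost without replicate 1 (adjusted p = 0.0729) and without ASO-Ctr replicate 1 (adjusted p = 0.0722), and DNMT3L without the block (adjusted p = 0.117). Of 32 proliferation genes 5 rose and 14 fell (6 and 14 adjusted over the list alone; camera adjusted p = 0.367), with the mitotic motors CENPE and KIF11 1.5-fold and 1.33-fold lower and the mitotic kinase PLK1 higher at log2 0.25. The other 4 that rose, CDC20, AURKA, CCNA2 and FOXM1, lost their calls without replicate 3 (adjusted p = 0.0717, 0.0803, 0.0723 and 0.119), FOXM1 also without ASO-Ctr replicate 3 (adjusted p = 0.0651) and without ASO-L1 replicate 3 (adjusted p = 0.0520), and CCNA2 and FOXM1 without the block (adjusted p = 0.0592 and 0.0634). Of 15 mitochondrially encoded genes MT-CYB, MT-ND6, MT-RNR1 and MT-ATP6 fell (3 adjusted over the list alone; camera adjusted p = 0.410), MT-CYB by 0.19 on the log2 scale. The list was called lower with no filter on low counts (adjusted p = 0.0434) and with 1 surrogate variable (adjusted p = 0.0119). MT-ATP6 lost its call in 12 of 16 leave-out fits (highest adjusted p = 0.215), MT-RNR1 without replicate 4 (adjusted p = 0.0677), and all but MT-CYB without the block (adjusted p = 0.130, 0.465 and 0.393).

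The change also followed the length of the gene. Over the 14497 genes (84.0% of those tested) whose genomic span and transcript could be looked up, the 2901 genes with the shortest span, a median of 4.07 kb, had a mean log2 difference of 0.10 ± 0.02 (SD over 4 replicate numbers), with 25.6% of genes higher and 13.3% lower. The 2900 genes with the longest span, a median of 174 kb, had a mean of -0.22 ± 0.04, with 10.5% higher and 45.9% lower.

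**Figure D2:**
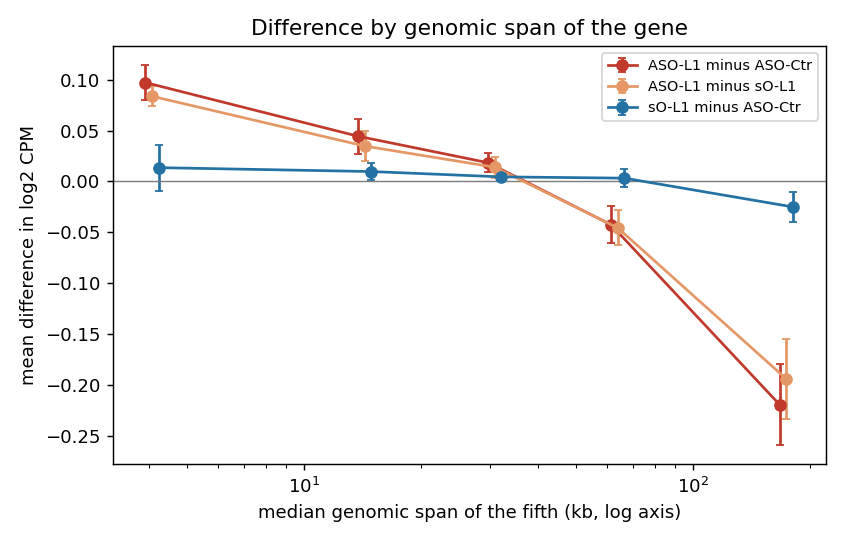
Mean difference in log2 CPM (y axis) of genes in 5 bins of genomic span, drawn at the median span of each bin in kb (x axis, log scale), for the 3 comparisons, with the mean ± SD of 4 replicate numbers. In ASO-L1 minus ASO-Ctr the mean lies at 0.10 in the shortest bin and at -0.22 in the longest, and in sO-L1 minus ASO-Ctr at 0.01 and -0.03.

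**Figure D3:**
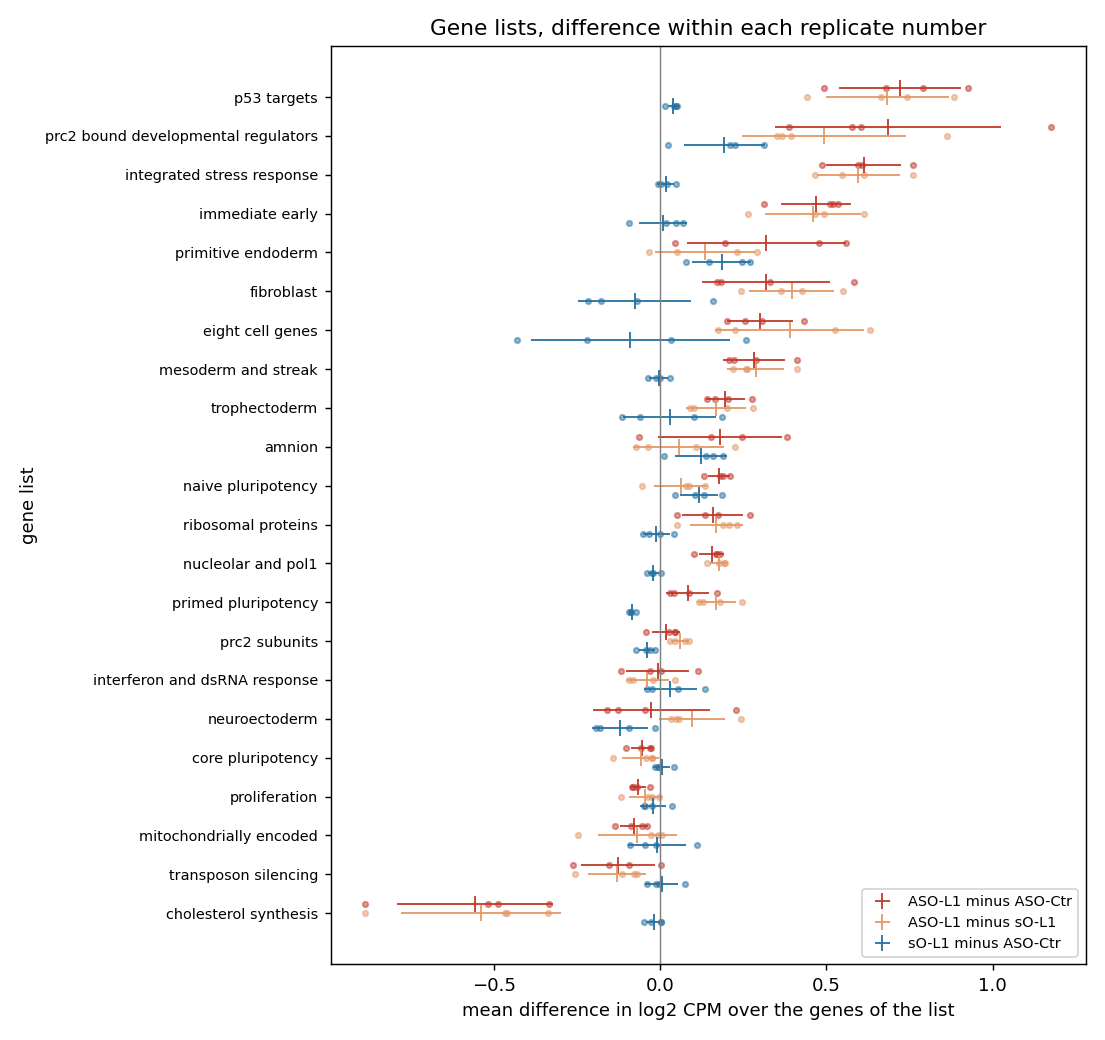
Mean difference in log2 CPM over the genes of each list (x axis) for the 22 lists (y axis) and the 3 comparisons, with a point per replicate number and a bar for the mean ± SD of 4. The p53 list lies at 0.72 ± 0.18 and the cholesterol list at -0.56 ± 0.23 in ASO-L1 minus ASO-Ctr, against 0.04 ± 0.02 and -0.02 ± 0.02 in sO-L1 minus ASO-Ctr.

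ASO-L1 against sO-L1 asks whether the same changes stand against the sense oligo of LINE1. The same leading genes rose: CCR7 at log2 6.06 (SE 0.29), ANXA1 at 4.55, HSPB8 at 2.99 (SE 0.15), FLNC at 2.61, AHNAK at 2.64 and VIM at 1.64. ATF5 was at log2 2.60, DDIT3 at 2.19, TRIB3 at 2.22, ATF3 at 1.88, CDKN1A at 2.24 and PHLDA3 at 1.46. HMGCS1 was at -0.85 and INSIG1 at -0.95, and SLC16A3 and FRMPD4 were at -1.85 and -1.48. EdgeR called 7602 of 17264 genes (44.0%), 3644 higher and 3958 lower, of which 395 and 267 differed by over 2-fold. In the authors' deposited table of this comparison 3354 genes were higher and 3492 lower at an adjusted p under 0.05. Over the 17264 genes in both, the log2 fold changes of the authors' deposited table and of this fit correlated across genes at r = 0.996 and had the same sign for 98.9%, and of 6586 genes called in the authors' deposited table this fit called 6564 in the same direction. ATF5, TRIB3, CDKN1A and ANXA1 stand in the authors' deposited table at log2 2.62, 2.24, 2.29 and 4.60.

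The gene lists called were the same 8. Against sO-L1, 23 integrated stress response genes rose and 4 fell (24 and 4 adjusted over the list alone; mean 0.60 ± 0.12), 22 p53 targets rose (22 adjusted over the list alone; 0.68 ± 0.19), 10 immediate early genes rose and EGR1 fell (11 and 1; 0.46 ± 0.15) and 22 cholesterol genes fell (22; -0.54 ± 0.24). The 4 stress response genes called lower were again CTH, ALDH1L2, PCK2 and DDIT4, of which DDIT4 and PCK2 turned to higher with 1 surrogate variable (log2 0.112 and 0.00519, not called). EGR1 lost its call in 4 of 16 leave-out fits (highest adjusted p = 0.0925), PCK2 in 4 (highest 0.0794), DDIT4 in 5 (highest 0.130), and ALDH1L2 without replicate 3 (adjusted p = 0.0839), without replicate 4 (adjusted p = 0.0788) and without sO-L1 replicate 4 (adjusted p = 0.0547). Camera gave adjusted p = 5.09e-18 for the stress response and for p53 targets, 1.21e-05 for immediate early genes and 5.60e-14 for cholesterol synthesis, and adjusted p = 0.162, 0.165, 0.165 and 0.367 with an estimated correlation. Of the ribosomal protein genes 57 rose and RPL26, RPL12 and RPL3 fell (61 and 3 adjusted over the list alone; 0.17 ± 0.08), and of the nucleolar list 42 rose and UTP20, HEATR1 and DDX21 fell (44 and 4; 0.18 ± 0.02). Camera gave adjusted p = 1.53e-09 and 3.44e-07, and adjusted p = 0.578 and 0.165 with an estimated correlation. NCL was higher by 0.15 on the log2 scale (adjusted p = 0.00120; without the replicate block adjusted p = 0.0642). Of the developmental regulators bound by PRC2 13 rose and SOX21 and PAX9 fell (13 and 3 adjusted over the list alone; 0.49 ± 0.25; camera adjusted p = 0.0164, and adjusted p = 0.518 with an estimated correlation). That call was lost without replicate 1 (adjusted p = 0.0787), without ASO-L1 replicate 1 (adjusted p = 0.0653), with a stricter filter of 1 CPM in 4 libraries (adjusted p = 0.0969) and with 1 surrogate variable (adjusted p = 0.507). The limit that the filter sets on the rises of this list, given above, holds here too. PAX9 lost its call in 7 of 13 leave-out fits (highest adjusted p = 0.156) and SOX21 without replicate 3 (adjusted p = 0.0545) and without the block (adjusted p = 0.606). Of the mesoderm list CER1, MIXL1, KDR and WNT3 rose (4 higher and 1 lower adjusted over the list alone; 0.29 ± 0.09; camera adjusted p = 0.0155, adjusted p = 0.165 with an estimated correlation, and adjusted p = 0.464 without the block), WNT3 losing its call in 7 of 16 leave-out fits (highest adjusted p = 0.159).

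Camera with the planned model did not call the remaining lists against sO-L1. Naive markers gave 7 higher and 7 lower (9 and 7 adjusted over the list alone; camera adjusted p = 0.471), with KLF4 at log2 1.05 and DPPA3 at 0.18 (adjusted p = 0.0276), whose call was lost in 8 of 16 leave-out fits (adjusted p = 0.000234 to 0.283) and without the block (adjusted p = 0.197). Primed markers gave 8 and 6 (8 and 6; adjusted p = 0.245) with ZIC2 at 1.39 and NLGN4X at -0.82, and core genes 5 and 8 (5 and 8; adjusted p = 0.493) with TERF1 at -0.64. The 5 core genes that rose were again FGF2, ZSCAN10, POLR3G, DPPA4 and DPPA2, of which DPPA2 lost its call in 13 of 16 leave-out fits (highest adjusted p = 0.242) and POLR3G without replicate 2 (adjusted p = 0.0676) and without sO-L1 replicate 2 (adjusted p = 0.0649). POU5F1 was at 0.05 (adjusted p = 0.353; called without replicate 1, 0.000844, and without ASO-L1 replicate 1, 0.00449), NANOG at 0.06 (adjusted p = 0.275) and SOX2 at -0.11 (adjusted p = 0.0256; lost in 9 of 16 leave-out fits, 0.00778 to 0.145, and without the block, 0.182). Of the PRC2 subunits EZH2 fell by 0.35 on the log2 scale (adjusted p = 1.97e-05), EED rose by 0.29 (adjusted p = 0.000745), PHF1 and C17orf96 rose and RBBP4 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.855), with SUZ12 at 0.03 (adjusted p = 0.598). C17orf96 and RBBP4 lost their calls in 7 and 5 of 16 leave-out fits (highest adjusted p = 0.148 and 0.0988). L1TD1 fell by 0.14 (adjusted p = 0.00351) and TRIM28 rose by 0.13 (adjusted p = 0.00718), the latter not called without replicate 3 (adjusted p = 0.0547) or without ASO-L1 replicate 4 (adjusted p = 0.0576).

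Against sO-L1, trophectoderm gave ABCG2, KRT18, GATA2, PGF and KRT8 higher (5 adjusted over the list alone; camera adjusted p = 0.211), PGF and KRT8 lost in 8 and 10 of 16 leave-out fits (highest adjusted p = 0.131 and 0.213). Amnion gave BMP4 lower at log2 -0.58 (1; adjusted p = 0.931). Primitive endoderm gave SPARC, LINC00261 and FOXA2 higher and PDGFRA, COL4A2, LAMA1 and COL4A1 lower (3 and 4; adjusted p = 0.831, pointing down with a median of 0.06 and a mean of 0.13), LAMA1 lost without replicate 3 (adjusted p = 0.0728) and COL4A1 in 8 of 16 leave-out fits (highest adjusted p = 0.161). Neuroectoderm gave SOX3, NES and PAX6 higher and DCX and TUBB3 lower (3 and 2; adjusted p = 0.896, pointing up with a median of -0.08 and a mean of 0.10). Fibroblast markers gave TAGLN, TWIST1, CTGF and S100A4 higher and COL1A2 and COL5A1 lower (4 and 2; adjusted p = 0.0892). TAGLN was at log2 1.60, TWIST1 at 2.77 and COL1A2 at -0.69. S100A4 lost its call in all 16 leave-out fits (adjusted p = 0.05003 to 0.188), CTGF without replicate 3 (adjusted p = 0.0655), and COL5A1 without replicate 2 (adjusted p = 0.111), without sO-L1 replicate 1 (adjusted p = 0.0733) and without ASO-L1 replicate 2 (adjusted p = 0.0844). Interferon response gave IFITM1, IFITM3, HERC5 and IFIH1 higher and 8 lower (4 and 8; adjusted p = 0.892, pointing down with a median of 0.10 and a mean of -0.02), IFIH1 lost in 9 of 16 leave-out fits (highest adjusted p = 0.248) and HERC5 without replicate 2 (adjusted p = 0.0934), without sO-L1 replicate 2 (adjusted p = 0.0586) and without ASO-L1 replicate 2 (adjusted p = 0.0579). Transposon silencing gave APOBEC3C, TRIM28, DNMT3L and TET2 higher and 11 lower (5 and 11; adjusted p = 0.341), DNMT3L lost without replicate 2 (adjusted p = 0.0551) and TET2 without replicate 2 (adjusted p = 0.0778) and without sO-L1 replicate 2 (adjusted p = 0.0691). Proliferation gave 7 higher and 11 lower (8 and 12; adjusted p = 0.589). Mitochondrially encoded genes gave MT-ND1 higher and 6 lower (1 and 6; adjusted p = 0.386), MT-ND1 lost in 6 of 16 leave-out fits (highest adjusted p = 0.141) and lower with 1 surrogate variable (log2 -0.0413, not called). This list was called lower with no filter (adjusted p = 0.0365) and with 1 surrogate variable (adjusted p = 0.0128). Without the replicate block, the calls of RBBP4, C17orf96, DPPA2, WNT3, KDR, ALDH1L2, PCK2, DDIT4, EGR1, PGF, KRT8, LINC00261, FOXA2, COL4A1, LAMA1, CTGF, S100A4, DNMT3L and MT-ND1 against sO-L1 were lost as well, at adjusted p-values from 0.0520 for RBBP4 to 0.467 for KRT8.

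Both comparisons share the ASO-L1 libraries, so part of their likeness comes from those. In the same direction in both, 6405 genes were called, 3056 higher and 3349 lower, and 10 in opposite directions. Independent lists of these sizes would share 774 and 913. Fold changes correlated across genes, which are not independent replicates, at r = 0.905 with 88.8% of signs alike and a covariance of 0.197. In 20 simulations of unchanged groups that share 1 set of libraries the values were r = 0.510, 66.9% and 0.0166. This leaves a covariance of 0.180. Simulated genes varied independently of one another around the replicate means. At most 0 genes were called against ASO-Ctr in any simulation. That at most 0 were shared follows from this and gives no measure of the overlap from shared libraries. With the ASO-L1 libraries split, replicates 1 and 2 against ASO-Ctr and 3 and 4 against sO-L1 gave 3564 shared genes of 5615 and 5543 called (902 for independent lists, r = 0.645, covariance 0.170), and the other way round 3792 of 5560 and 5694 (917, r = 0.669, covariance 0.175).

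sO-L1 against ASO-Ctr asks whether the sense oligo itself differs from the non-targeting oligo. EDA, a ligand of the tumour necrosis factor family, was 2.50-fold lower with sO-L1 at 5.00 ± 0.496 against 12.4 ± 0.601 CPM (log2 -1.32, SE 0.10, adjusted p = 3.84e-06, edgeR). GRIP1, a synaptic scaffold, was 2.01-fold lower at 6.04 ± 0.908 against 12.1 ± 0.224 CPM (adjusted p = 5.63e-05), MMP16, a membrane metalloprotease, 1.91-fold lower at 6.94 ± 1.59 against 13.2 ± 1.99 CPM (adjusted p = 5.35e-05) and MYO6, an unconventional myosin, 1.57-fold lower at 66.9 ± 7.62 against 105 ± 8.97 CPM (adjusted p = 1.17e-05). PPP2R3A, a phosphatase subunit, was 1.54-fold higher at 31.0 ± 1.62 against 20.1 ± 2.65 CPM (adjusted p = 0.000167). These 5 genes were called in all 16 leave-out fits. Both this comparison and that of ASO-L1 use the same ASO-Ctr libraries, so a like direction in both is partly given by those, and no value without an effect was computed for it. With ASO-L1, EDA, GRIP1 and MMP16 were lower than with ASO-Ctr (log2 -0.99, -0.92 and -0.50), each called in all 16 leave-out fits. PPP2R3A was higher (log2 0.28, adjusted p = 0.00396). Its call was lost without replicate 3 (adjusted p = 0.0631) and with 1 surrogate variable (adjusted p = 0.146). MYO6 was at -0.12 (adjusted p = 0.0905). It was called lower without replicate 1, without ASO-Ctr replicate 1 and without ASO-L1 replicate 1, with a highest adjusted p of 0.0349. It was also called with 1 surrogate variable (adjusted p = 0.000258) and on the authors' log2 table (adjusted p = 0.00532). In all edgeR called 50 of 17264 genes (0.290%), 12 higher and 38 lower. The 4 that differed by over 2-fold were EDA, GRIP1, HMCN1 and IMMP2L, all lower, of which HMCN1 and IMMP2L lost their calls in 8 and 10 of 16 leave-out fits (highest adjusted p = 0.336 and 0.329) and without the block (adjusted p = 0.0703 each).

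The count of 50 depended on single libraries and settings. It was 241, 10, 10 and 31 without replicates 1 to 4. Without ASO-Ctr replicates 2, 3 and 4 it was 21, 21 and 29, without sO-L1 replicates 2, 3 and 4 it was 21, 21 and 25, without ASO-L1 replicate 1 it was 410, it was 17 without the replicate block, and it was 640 when only the libraries of these 2 groups were fitted. SOX21, a neural factor, was higher at log2 0.77 (adjusted p = 0.000475), and was not called without replicate 3 (adjusted p = 0.0631) or without the block (adjusted p = 1). It was the 1 gene called by edgeR among the 494 tested members of the 22 lists, of which 51 had an unadjusted p under 0.05, and DESeq2 called 3 and limma, run on the authors' log2 table, called 10. Adjusted over the list alone, 1 naive, 1 mesoderm, 1 neuroectoderm and 1 PRC2-bound gene were higher, and 1 primed, 1 primitive endoderm, 1 neuroectoderm and 2 fibroblast genes were lower.

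Camera called 4 lists for sO-L1 against ASO-Ctr, all by small amounts. Primed markers were lower by a mean of -0.09 ± 0.01 (adjusted p = 0.000122), developmental regulators bound by PRC2 higher by 0.19 ± 0.12 (adjusted p = 0.00221), naive markers higher by 0.12 ± 0.06 (adjusted p = 0.0342) and fibroblast markers lower by -0.08 ± 0.17 (adjusted p = 0.0443). With an estimated correlation these were adjusted p = 0.162, 0.435, 0.165 and 0.367. The naive call was lost in 14 of the 16 leave-out fits and the fibroblast call in 8, and without the replicate block both were lost (adjusted p = 0.230 and 0.104), with highest values over the leave-out fits of 0.309 and 0.281. The PRC2-bound call was lost with no filter on low counts (adjusted p = 0.520), on the authors' log2 table (adjusted p = 0.251), with fry (adjusted p = 0.187) and without ASO-Ctr replicate 1 (adjusted p = 0.0526). The number of lists called was 2 without ASO-Ctr replicate 1, without sO-L1 replicate 2 or without ASO-L1 replicate 1, and 7 without sO-L1 replicate 1. Those 7 included p53 targets and the integrated stress response, higher (adjusted p = 0.0313 and 0.0441), and cholesterol synthesis, lower (adjusted p = 0.00568). These are the directions seen with ASO-L1. The p53 targets were also called higher without ASO-Ctr replicate 4 (adjusted p = 0.00685), and no other leave-out fit called these 3 lists. Nucleolar genes were called lower in 5 alternatives (adjusted p = 0.00631 to 0.0444), ribosomal proteins in 3 (0.00183 to 0.0472) and proliferation in 2 (0.00227 and 0.00513). Fry called amnion higher (adjusted p = 0.0290). For the other lists camera gave adjusted p = 0.833 for core genes, 0.831 for PRC2 subunits, 0.0843 for nucleolar genes, 0.575 for ribosomal proteins, 0.399 for interferon response, 0.211 for p53 targets, 0.370 for the integrated stress response, 0.831 for cholesterol synthesis and 0.855 for immediate early genes. It gave 0.671 for trophectoderm, 0.248 for amnion, 0.405 for primitive endoderm, 0.471 for mesoderm, 0.485 for neuroectoderm, 0.896 for mitochondrially encoded genes, 0.831 for transposon silencing and 0.207 for proliferation. The direction of the test differed in sign from the median or the mean for PRC2 subunits, mitochondrially encoded genes, transposon silencing, immediate early genes and mesoderm, all within 0.04 of 0. As a limit to the camera results of all 3 comparisons, regrouping the libraries of 2 groups across their labels also gave list calls with the preset correlation, where the real groups gave 8 lists for ASO-L1 against ASO-Ctr, 8 against sO-L1 and 2 for sO-L1 against ASO-Ctr in 2-group fits. Among the other splits that part all 4 replicate numbers as many as 7, 8 and 2 lists were called, and among the 24 that part 2 of them as many as 8, 10 and 4. For both ASO-L1 comparisons the highest counts came from splits that keep most libraries of each group together. Such splits still carry the real effect. Those with 2 libraries of each group on either side gave at most 3 and 5 lists.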

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

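The count by replicate number in this section was chosen after the result was seen. So were some of the genes examined, since these are genes that the text names. The test for a library far from the other 3 of its group was itself set before the data were examined. It was applied to 495 groups of 4 values, of which chance alone gives about 1 in 20, or 24.75, and 27 were found. That chance number is for independent groups, which these are not, since genes and lists of the same library vary together. It also takes no account of the choice of genes after their values were seen. Of the 27, 18 were in replicate 1, with 5 in ASO-Ctr, 5 in sO-L1 and 8 in ASO-L1, where an even spread over the 4 replicate numbers would give 6.75. Replicate 1 thus stood apart more often than the others in each group. No explanation was tested for any of them. Values are log2 CPM except where another unit is given, with the range of the other 3 libraries of the group in brackets.

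Among markers of cell state, ASO-Ctr replicate 1 had the highest mean of the naive list, 3.97 (3.57 to 3.60), sO-L1 replicate 1 the highest mean of the core pluripotency list, 8.34 (8.24 to 8.25), and ASO-L1 replicate 1 the highest mean of the trophectoderm list, 2.98 (2.69 to 2.73). KRT8, a keratin of simple epithelia, was highest in replicate 1 of all 3 groups, at 8.81 in ASO-Ctr (8.44 to 8.46), 8.88 in sO-L1 (8.47 to 8.5) and 8.86 in ASO-L1 (8.62 to 8.64). POU5F1 was highest in sO-L1 replicate 1, 10.32 (10.18 to 10.19), and NANOG lowest in sO-L1 replicate 2, 6.91 (7.16 to 7.20). In ASO-L1 replicate 1 HOXB3 was at 1.37 (-0.07 to 0.06), PAX6 at 2.05 (1.32 to 1.41), FGF2 at 8.05 (7.56 to 7.62) and ZSCAN10 at 7.94 (7.70 to 7.73), all highest. PAX6 was lowest in ASO-Ctr replicate 2, 0.35 (1.02 to 1.08), SOX3 lowest in sO-L1 replicate 4, -0.19 (0.64 to 0.80), and PDGFRA highest in ASO-Ctr replicate 3, 4.02 (3.92 to 3.92).

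Among stress, ribosome and other genes, ASO-Ctr replicate 1 had the highest CDKN1A, 3.42 (2.07 to 2.16), the lowest UTP20, 7.05 (7.34 to 7.39), and the lowest CTGF, 6.43 (6.70 to 6.75). RPLP1 was highest in ASO-L1 replicate 1, 9.91 (9.78 to 9.79), and RPL12 in sO-L1 replicate 1, 8.95 (8.79 to 8.81). GAPDH was highest in sO-L1 replicate 1, 10.88 (10.66 to 10.69), and lowest in ASO-L1 replicate 1, 10.78 (10.89 to 10.90). CENPE, PPP2R3A and POLR3G were highest in ASO-Ctr replicate 2, at 6.91 (6.65 to 6.69), 4.59 (4.2 to 4.26) and 6.65 (6.60 to 6.61), and MYO6 in sO-L1 replicate 2, 6.29 (5.96 to 6.02). sO-L1 replicate 2 also had the most reads, 55.1 M (31.1 to 34.8 M).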

How the results depend on the processing

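No tests here were chosen after the result was seen except the sum of the 8C genes under the filter, which is given in the report. For the counts of genes and lists and the 8C list, 224 values under an alternative kept their side of the threshold or stayed within 1.5 times. Another 33 moved further and 2 passed the threshold only under the alternative. A change of direction of the 8C list was counted only where a fit called it. The 3 sums of 8C genes under the filter were put among the 224 without a check. Their differences (-0.0216, -0.0430 and 0.0214 CPM) had the opposite sign to the mean of the tested 8C genes in each comparison. For 374 pairs of a named gene and a comparison, 8619 of 9329 values kept their side of the threshold, 652 lost the call and 51 gained it. A further 7 changed sign with a call in either fit. A change of sign of a gene called in neither fit counts among the 8619. Unless said otherwise, the cause was not tested.

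For sO-L1 against ASO-Ctr, 50 genes were called in the model with the replicate block. Without the replicate block 17 were called, all among the 50. DESeq2 called 95, no filter on low counts 141, only the 2 groups compared 640, the authors' log2 table with limma-trend 209 and 1 surrogate variable 484, each including the 50. The count of 209 can be too high, since limma-trend had no replicate block on values already corrected for batch. Leaving out a replicate or library gave 10 to 410. Camera called 4 lists for this comparison, 2 without the replicate block, 2 with no filter, 2 with only the 2 groups, 2 on the authors' log2 table and 2 to 7 when a replicate or library was left out.

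For ASO-L1, 1 surrogate variable gave 4244 genes against ASO-Ctr, 4606 against sO-L1 and 3531 in both, against 7652, 7602 and 6405. Without the replicate block these counts were 5893, 5782 and 4826, and leave-out fits gave 5797 to 7849, 5747 to 7810 and 4668 to 6684. With the surrogate variable KDR at -0.0703, RPL3 at 0.0135, DDIT4 at 0.196 and PCK2 at 0.0480 against ASO-Ctr, and DDIT4 at 0.112, PCK2 at 0.00519 and MT-ND1 at -0.0413 against sO-L1 changed sign on the log2 scale and were not called.

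An estimated correlation left 0, 0 and 0 lists called by camera in the 3 comparisons, against 8, 8 and 4. Fry, which does not compare a list with other genes, called 15 and 14 lists in both ASO-L1 comparisons, and the 8C list at adjusted p = 0.0439 and 0.0253, where camera gave 0.565 and 0.524. In leave-out fits camera called 8 to 8 lists against ASO-Ctr and 7 to 8 against sO-L1, and the 8C list had adjusted p from 0.496 to 0.695, 0.407 to 0.749 and 0.470 to 0.968. Of the 54 8C genes in the table, a total of 51 lay under the filter, where depth and reads shared between near-identical copies both limit what can be seen.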

Other observations

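In this part, the tests of fibroblast-like cells and of the stress lists, the splits for the counts of genes, and the tests of the 3 gene lists in the next paragraph were chosen only after the result was seen.

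Host genes of small nucleolar RNAs, whose spliced RNA is unstable and is degraded during translation, rose with ASO-L1. Of 16 such genes 14 rose and SNHG14 fell (log2 -0.30) against ASO-Ctr, with a mean log2 difference of 0.58 ± 0.20 (SD over 4 replicate numbers, camera adjusted p = 2.67e-10, and adjusted p = 0.352 with an estimated correlation). SNHG1 rose from 273 ± 7.58 to 566 ± 190 CPM (log2 1.01, SE 0.11, adjusted p = 1.24e-06, edgeR), SNHG8 from 41.2 ± 1.16 to 80.8 ± 14.4 CPM and GAS5 from 210 ± 5.74 to 347 ± 73.0 CPM. Against sO-L1 14 rose and SNHG14 fell as well (0.55 ± 0.23). Of 28 targets of the hypoxia factor HIF, 14 fell, and VEGFA, NDRG1, SLC2A3, GAPDH and ADM rose, with a mean of -0.23 ± 0.18 (camera adjusted p = 0.00764, and adjusted p = 0.739 with an estimated correlation). BNIP3, a mitophagy receptor, was at 30.7 ± 7.27 against 67.8 ± 15.9 CPM (log2 -1.12, SE 0.11, adjusted p = 3.89e-07) and the kinase PDK1 at 43.7 ± 5.65 against 79.6 ± 16.3 CPM. Against sO-L1 14 fell and the same genes without NDRG1 rose (camera adjusted p = 0.00240, and adjusted p = 0.739 with an estimated correlation). GAPDH lost its call against ASO-Ctr without replicate 2 (adjusted p = 0.0579) and without replicate 3 (adjusted p = 0.0556), and against sO-L1 in 9 of 16 leave-out fits (highest adjusted p = 0.154), while NDRG1 was called against sO-L1 without replicate 3 (adjusted p = 0.0303), without sO-L1 replicate 3 (adjusted p = 0.0183) and without ASO-L1 replicate 3 (adjusted p = 0.0498). Without the replicate block VEGFA and ADM were not called against ASO-Ctr (adjusted p = 0.177 and 0.0618). Of 447 numbered ZNF genes 171 rose and 58 fell (0.12 ± 0.12; camera adjusted p = 0.00205, and adjusted p = 0.739 with an estimated correlation). These lists were made from genes seen to change, so their p-values are no independent evidence.

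Genes with a longer genomic span had lower RNA with ASO-L1. The log2 difference from ASO-Ctr had a slope of -0.05004 ± 0.00617 per doubling of span (SD over 4 replicate numbers, negative in 4 of 4). Transcript length, GC content and mean expression do not account for it, since with these in the model the slope was -0.0607 ± 0.0218. Transfecting any LINE1 oligo does not account for all of it either. The adjusted slope of sO-L1 against ASO-Ctr was -0.00651 ± 0.00191, negative in 4 of 4 replicate numbers. With sO-L1, 29 of the 2900 genes with the longest span were called lower than with ASO-Ctr and 3 higher. No other bin of span had more than 6 called lower. Both comparisons share the ASO-Ctr libraries, which can give part of a like direction. A small part common to both LINE1 oligos is thus neither shown nor excluded. Slower or interrupted transcription of long genes, and binding of the oligo to LINE1 copies in introns, could each give such a slope, but positions of LINE1 copies were not used here and both stay hypotheses.

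ANXA1, AHNAK, FLNC and VIM, genes that fibroblasts express highly, rose with ASO-L1 by 483 ± 223 CPM in sum. Fibroblast-like cells among the sorted cells, which a sort on the label of the oligo would not remove, would bring collagen RNA with them. The summed level of the collagens COL1A1 and COL1A2 fell by 23.8 ± 9.78 CPM, -4.99% of that rise, which argues against such cells as the whole cause. A response of the ES cells to loss of LINE1 RNA, which was not tested, and an effect of this 1 antisense sequence on other RNAs both stay open, since no second sequence was used.

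The p53 targets and integrated stress response genes rose and cholesterol genes fell with ASO-L1. A response common to all 3 oligos cancels in these differences, and no group without an oligo was there to show it. A response shared by both LINE1 oligos as the whole cause is argued against by sO-L1. Its mean difference from ASO-Ctr was 5.34, 2.56 and 3.33% of that of ASO-L1 in size for the 3 lists. With all libraries none of the 3 lists was called for sO-L1 (camera adjusted p = 0.211, 0.370 and 0.831, and adjusted p = 0.863, 0.863 and 0.934 with an estimated correlation). The direction was that of ASO-L1 in 4, 3 and 2 of 4 replicate numbers. Of 16 leave-out fits, the one without sO-L1 replicate 1 called all 3 (adjusted p = 0.0313, 0.0441 and 0.00568) and the one without ASO-Ctr replicate 4 called p53 targets (adjusted p = 0.00685). A small response to sO-L1 is thus neither shown nor excluded. The share of reads taken by a few genes is argued against as well: the 20 most abundant genes took 9.10 ± 0.272% in ASO-Ctr, 9.16 ± 0.330% in sO-L1 and 9.03 ± 0.342% in ASO-L1. The log2 shift of all other genes that this share gives was at most 2.29% of a list mean in size, over the 3 lists, both controls and 4 replicate numbers. Loss of LINE1 RNA and an effect of the antisense sequence on other RNAs could both lead to such a response, and no value here separates them.

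Other splits of the libraries were set beside the real groups. The 8 splits of each pair of groups that part all 4 replicate numbers are too few for a share under 0.05, the smallest being 0.125. In 2-group fits the real groups gave 6758 genes for ASO-L1 against ASO-Ctr, 6525 against sO-L1 and 640 for sO-L1 against ASO-Ctr, and the highest of the other splits 0, 0 and 1, so that 1, 1 and 1 of 8 gave as many. For gene lists with the preset correlation the real values were 8, 8 and 2 and the highest others 7, 8 and 2, with 1, 2 and 5 of 8 as large. For the size of the mean 8C difference they were 0.322, 0.403 and 0.0677, with highest others of 0.218, 0.300 and 0.268, and 1, 1 and 6 of 8 as large. The 24 splits of each pair of groups that part 2 of the replicate numbers gave at most 0, 0 and 59 genes. They gave as many as 8, 10 and 4 lists, with 2, 6 and 18 of 24 at or above the real count. Their 8C means reached 0.398, 0.629 and 0.376, with 6, 8 and 20 of 24 at or above the real mean. Each of the 24 has a mirror among them with the same fit, so every regrouping counts 2 times in these shares. The replicate block takes up the numbers that are not parted, so only the 2 parted ones enter. For both ASO-L1 comparisons every other value at or above the real one came from a split that keeps most libraries of each group together. Such splits still carry the real effect. Those with 2 libraries of each group on either side gave at most 3 and 5 lists and 8C means of 0.145 and 0.227. For sO-L1 against ASO-Ctr such evenly mixed splits reached 3 lists and an 8C mean of 0.365, above the real values. For the overlap of both ASO-L1 comparisons 40 of the 648 possible relabelings within replicate numbers were run, and 1 of 40, the real one, gave a count as large, 6405 against at most 0 in the others. If the labels meant nothing, the real one would rank highest in 1 of 40 such sets, a share under 0.05. Chance in the grouping of these libraries is thus unlikely for it, but not excluded. In mixed groups, however, the real effect adds to the spread and lowers the count, and the test does not reach beyond these libraries if the replicates are technical.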
